A study of Mus musculus with 9 samples.

How the data were processed

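Bulk RNA-seq was analysed in 9 libraries of G1E cells, a mouse erythroid progenitor line that lacks functional Gata1. The cells had received a viral vector that was empty, carried human wildtype GATA1 or carried a human GATA1 mutant. Each of the 3 groups had 3 libraries, which the series describes as biological replicates, and groups and replicate numbers were taken from the sample labels. The labels do not name the mutation, the time between infection and lysis, or any selection of infected cells, and these are not given in the sources used here. Libraries were made from total RNA with Smart-seq2, a full-length method that primes cDNA on the poly(A) tail and keeps no strand, and were indexed with a Nextera-based (transposase) step, per the labels' protocols.

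The authors deposited one table of raw counts of reads per gene. It held 27999 rows, of which 27998 were mouse genes and 1 was human GATA1. The aligner was STAR and the genome builds were GRCm38.p4 for mouse and hg19 for human, per the submitters' processing notes. The STAR version, the counting tool, the annotation and the treatment of reads that match several genes are not given in the sources used here. A symbol was repeated on 65 rows, covering 56 symbols; these rows were kept apart. A further property of the table was that 12975 rows had no count in any library. No row was a total or a class of unassigned reads.

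Library totals ranged from 11364358 to 17289307 counts. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to 0.174 to 0.264 CPM (counts scaled to a common library total) in single libraries. Intervals at the 95% level and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group had no counts, a fold was computed against 3 counts over the whole group; where a group had 1 to 3 counts, a ratio with its exact counting interval was given.

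Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for the gene list tests. Normalization factors were computed by TMM, genes were filtered by filterByExpr with the groups, and 9978 genes were tested. A quasi-likelihood model (glmQLFit, glmQLFTest) with 1 mean per group was fitted to all 9 libraries, leaving 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each of 3 comparisons. A gene was called higher or lower at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F-statistic. They are therefore approximate and were not estimated for the coefficient itself. CPM values used TMM-scaled library sizes except for human GATA1 (library totals), and log2 CPM used a prior count of 2. P-values measure the spread between these libraries.

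A total of 20 gene lists was fixed. One of them held the 12 display genes, the other 19 held 583 members, and 18 had enough tested members for a set test; the lymphoid list had 2. The set test was limma's camera with a preset correlation between genes of 0.01, and it was repeated with a correlation estimated from the data. Lists with at least 3 tested members were tested, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of called members were taken both from the adjustment over all genes and adjusted over the list alone.

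The groups, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named 12 display genes whatever their result. For each comparison it added the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change, given a mean of at least 5 CPM over the 6 libraries and no overlap of the groups. Predicted genes named Gm with a number, Rik clones, pseudogenes and identifiers with no symbol were left out of that part. From each list, the 3 tested members with the smallest unadjusted p were added per comparison. Some genes that this rule names are not reported here. Gene symbols are those of the table, which pairs them with no identifier; coordinates are those of GENCODE M21 on GRCm38 for symbols with 1 match there.

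The overlap of the responses to wildtype and mutant GATA1 was set beside 30 simulations of unchanged groups sharing the same empty vector libraries and drawn without the pairing of mutant and wildtype described below; the covariance that the pairs add, and 30 simulations that keep the wildtype effect, were added after seeing the data. The relative response to the mutant was cross-fitted: genes were called from 2 libraries per group, and the mean log2 difference from empty vector was measured in the library left out, over 3 folds. The tests were checked on simulated counts drawn from the means and dispersions of these libraries. For the wildtype comparison (9836 simulated genes tested), genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered at 26.5%, 70.0%, 100% and 100%, and 5.16% of calls were false. For the mutant comparison (9833 genes), the recovery was 28.6%, 81.6%, 98.0% and 98.0%. A simulated relative response of 25% was recovered as 23.0% for genes higher and 25.7% for genes lower (9978 genes). In these checks each gene was drawn on its own, without the library trend or the close pair of mutant replicates described below. The recovery and false-call rates therefore need not hold for the real libraries.

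Replicates were compared by a chi-square test of their counts over genes with a summed count of at least 20. Mutant replicates 1 and 2 had a chi-square of 2.21 per degree of freedom, against 15.0 to 55.5 for the other 8 pairs within groups. This test cannot tell repeat libraries of 1 sample from separate samples, and each library was kept as a sample because the series describes biological replicates. Mutant replicates 1 and 2, whose median absolute log2 difference was 0.078 against 0.186 to 0.340 in the other pairs, may come from 1 sample, and the p-values may then understate the spread.

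Groups share the replicate numbers 1 to 3, which come from the labels and are tied there to no batch or day. Deviations from group means of like-numbered mutant and wildtype libraries correlated over genes at 0.171, 0.286 and 0.533, each above 0.1. These groups were therefore treated as paired by number, and their comparison was refitted to its 6 libraries with the pair as a block. The pairing is an assumption drawn from the same deviations that the block removes, so calls gained with the block do not test it. In both groups replicate 3 lay opposite replicates 1 and 2 on the leading component of these deviations, described below. That alone can raise such correlations.

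Alternatives were RLE factors, DESeq2 1.42.0, no low-count filter, a filter at 5 CPM in 3 libraries, a fit to the 6 libraries of the compared groups (4 residual degrees of freedom), the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were 1 surrogate variable from sva 3.50.0, loess offsets for transcript length and GC content (span 0.5; 9676 of the tested genes, 97.0%, had both), a fit with mutant replicates 1 and 2 summed, and the paired fit of the mutant against the wildtype, with and without the length and GC offsets. Single values were compared by exact permutation tests in scipy 1.17.1.

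Several properties of the data limit the reading of single genes. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies, and how shared reads were divided between them is not given in the sources used here. The mouse Gata1 row can hold reads of the human transgene that match the mouse gene, and vice versa. Overlapping and antisense genes cannot be told apart in libraries that keep no strand.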

Results

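RNA was measured in G1E cells that had been infected with an empty vector, with human wildtype GATA1 or with a human GATA1 mutant. GATA1 is the transcription factor that drives erythroid maturation, and G1E cells are arrested as progenitors because they lack it. They were grown with stem cell factor and erythropoietin. Each group held 3 libraries. Totals were 17289307, 16282638 and 14788962 counts for mutant replicates 1, 2 and 3, 13103114, 11439859 and 11364358 for wildtype replicates 1, 2 and 3, and 13659747, 13995254 and 15052013 for empty vector replicates 1, 2 and 3. The comparisons ask what each form of GATA1 changed against the empty vector, and how the mutant differed from the wildtype.

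Human GATA1 RNA was present in both groups that had received it. It stood at 817 ± 103 CPM with the wildtype and at 653 ± 53.9 CPM with the mutant (SD, n = 3). The mutant mean was 79.8% of the wildtype mean, and the exact permutation test of the difference gave a two-sided p of 0.1, which is the smallest that 3 against 3 libraries allow. The single libraries held 653, 706 and 598 CPM with the mutant and 816, 715 and 921 CPM with the wildtype. With the empty vector, 2 counts fell on the human gene in replicate 2 and 0 counts in the other libraries. The CPM ratio to empty vector was 17449 for the wildtype (counting interval 4830 to 144086) and 13971 for the mutant (3867 to 115364).

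The mouse Gata1 gene (GRCm38, chromosome X, 7959260 to 7978071, minus strand) was not called in any comparison. Its mean was 39.6 CPM with the empty vector, 47.1 CPM with the wildtype and 48.9 CPM with the mutant. This row can hold reads of the transgene and of transcripts from the disrupted locus, so it checks neither.

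**Figure D1:**
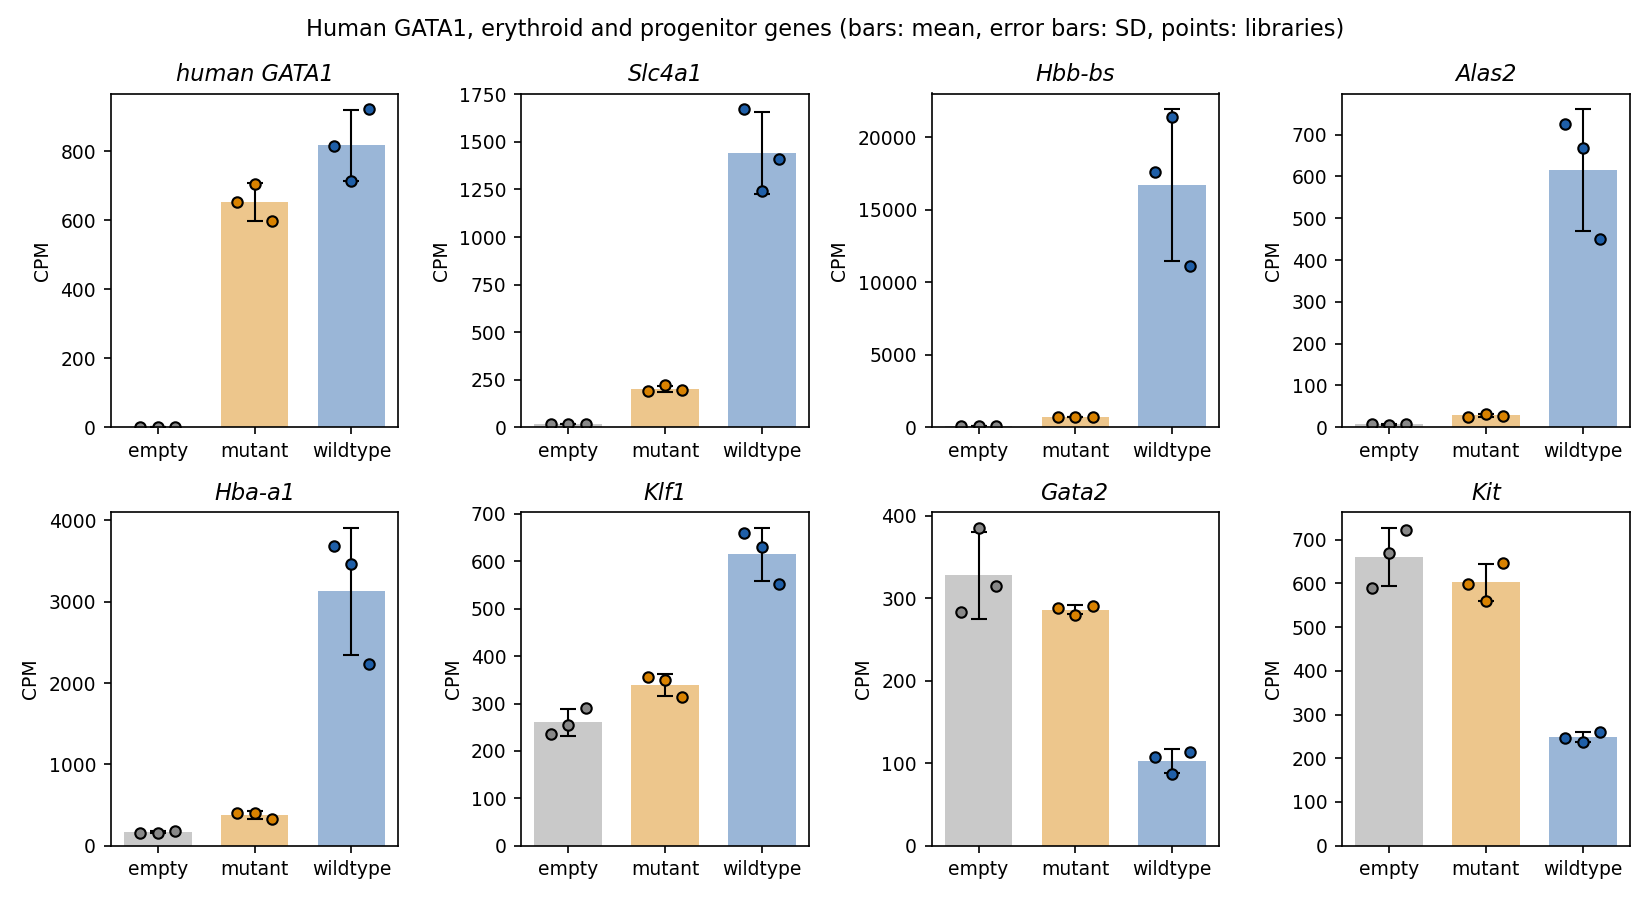
CPM of human GATA1 and 7 mouse genes, 1 panel per gene with CPM on the y axis (linear, from 0); bars are group means, error bars the SD and points the 3 libraries of each group. Human GATA1 lay at 653 CPM with the mutant and 817 CPM with the wildtype, while mean Slc4a1 was 200.4 and 1441 CPM, and Hba-a1 376 and 3128 CPM.

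Wildtype GATA1 raised most tested genes of hemoglobin production and of the red cell membrane. Slc4a1, the band 3 anion exchanger, rose from 16.7 ± 2.03 CPM with the empty vector to 1441 ± 216 CPM (SD, n = 3), an 86.0-fold change. Hbb-bs, an adult beta-globin gene, rose from 76.7 ± 10.9 to 16691 ± 5214 CPM, or 218-fold. Alas2, the erythroid enzyme of the first step of heme synthesis, rose 88.3-fold, from 6.97 ± 0.869 to 615 ± 146 CPM. Gata2, a progenitor transcription factor, fell from 328 ± 52.3 to 103 ± 14.3 CPM, and Kit, the receptor for stem cell factor, from 661 ± 66.2 to 248 ± 11.7 CPM.

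In the edgeR quasi-likelihood test, 1137 genes were higher and 1186 lower with wildtype GATA1 among 9978 tested, at least 2-fold for 426 and 391 of them. The groups did not overlap for 32.6% of genes, against 10% by chance if all libraries were exchangeable. Without empty vector replicate 2 the counts were 732 higher and 706 lower, and without wildtype replicate 1 there were 655 lower.

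Among called genes with a mean of at least 5 CPM over the 6 libraries and no overlap of the groups, Mybpc3, Hba-x, Tubb1 and Hbb-y had the largest positive log2 fold changes. Mybpc3, a myosin-binding protein known from heart muscle (chromosome 2, 91118144 to 91136516), had 0 counts with the empty vector and was at least 858-fold higher. Hba-x, the embryonic zeta-globin, was at least 491-fold higher on the same floor of 3 counts over the group. Tubb1, a beta-tubulin of platelets, had 1 count with the empty vector and a ratio of 1623 (counting interval 291 to 64140). Hbb-y, the embryonic epsilon-globin, had 3 counts there and a ratio of 596 (204 to 2895). Hbb-bh1, Dmtn (dematin, an actin-bundling membrane skeleton protein), Hba-a2 and Slc38a5 (an amino acid transporter) had log2 fold changes of 8.70 ± 0.34, 8.07 ± 0.30, 8.03 ± 0.48 and 6.72 ± 0.31 (SE). Under the same limits, and with Rik clones left out, the largest falls were those of Cpa3 (mast cell carboxypeptidase A, log2 fold change −3.01 ± 0.18), Fgl2 (−2.69 ± 0.29), Tec (a tyrosine kinase, −2.65 ± 0.19) and Gsn (gelsolin, −2.57 ± 0.20). Rab44 (−2.33), Lcp2 (−2.29), Ikzf2 (−2.18), Papss2 (−2.10), Rnase6 (−2.08) and Fgf3 (−2.06) followed. Their adjusted p-values in edgeR ran up to 0.0018, that of Ikzf2.

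All 8 tested globin genes rose, with a median log2 fold change of 7.90 when genes with no count in the empty vector are set at their bound. Of 28 genes of heme synthesis and iron handling, 17 rose and 1 fell (19 and 1 adjusted over the list alone). The fall was lost without mutant replicates 1 or 2, without any 1 wildtype library and without empty vector replicates 2 or 3. Beside Alas2 these were led by Fam132b, the iron hormone erythroferrone (5.56 ± 0.20), and Slc25a37, the mitochondrial iron importer mitoferrin (3.63 ± 0.15). Of 26 genes of the erythroid membrane and cytoskeleton, 19 rose and 7 were not called (20 higher and 1 lower adjusted over the list alone), among them Tmcc2 (3.89 ± 0.16). In camera the adjusted p-values of these lists were 2.8e-54, 5.4e-28 and 5.1e-48, and they were 0.00108, 0.00502 and 0.00378 with an estimated correlation.

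Of 23 erythroid transcription factors and receptors, 10 rose and 2 fell (12 and 2 adjusted over the list alone), with 6 higher without wildtype replicate 1 or empty vector replicate 2. Klf1, the erythroid Kruppel-like factor, rose by 1.24 ± 0.12 and E2f2 by 1.33 ± 0.14 on the log2 scale, while Stat5a, a signal transducer of the erythropoietin receptor, had −1.41 ± 0.13. The list passed camera at an adjusted p of 0.00518, but had an adjusted p = 0.259 with an estimated correlation. Zfpm1, the GATA1 cofactor FOG1 (0.05 ± 0.22), and Spi1, the myeloid factor PU.1 (0.25 ± 0.13), were not called.

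Most called members of the progenitor, mast cell, megakaryocyte and granulocyte lists fell. Of 20 progenitor regulators, 11 fell and 1 rose (13 and 1 adjusted over the list alone), led by Kit (−1.41 ± 0.12), Gata2 (−1.67 ± 0.14) and Hhex (−1.54 ± 0.14), with a camera adjusted p of 6.1e-08, or 0.0454 with an estimated correlation. Of 11 mast cell and basophil markers, 6 fell and 2 rose (7 and 2 adjusted over the list alone); Il1rl1, the IL-33 receptor, had −1.88 ± 0.15. The list had an adjusted p of 0.000246, or 0.0391 with an estimated correlation. Of 12 megakaryocyte markers, 9 fell, including Pf4 (platelet factor 4, −1.73 ± 0.20) and Nrgn (−1.19 ± 0.15), and 1 rose, which was Tubb1; the counts were equal adjusted over the list alone. The adjusted p of 0.00525 became an adjusted p = 0.0993 with an estimated correlation. Of 8 granulocyte and monocyte markers, 5 fell (5 adjusted over the list alone), among them Fcgr3 (−2.64 ± 0.29) and Tyrobp (−2.54 ± 0.40), at adjusted p 0.00525 and adjusted p = 0.056 with an estimated correlation. With the filter of 5 CPM in 3 libraries, 0 of these markers were called. Only 2 lymphoid markers were tested: Gata3 fell (−2.28 ± 0.26) and Lck rose (0.74 ± 0.24), a call that was lost without mutant replicate 2, wildtype replicates 1 or 2, or empty vector replicates 1 or 2, with adjusted p-values from 0.0213 to 0.164 over the alternatives.

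Growth and stress genes changed in both directions. Of 39 genes of mitosis, 11 rose and 1 fell (11 and 1 adjusted over the list alone), led by Cdc25b, a phosphatase that promotes entry into mitosis (2.62 ± 0.15), and Ube2c (0.86 ± 0.10); camera gave an adjusted p of 0.00179 and adjusted p = 0.0664 with an estimated correlation. Of 16 cell cycle arrest genes, 3 rose and 3 fell (4 and 5 adjusted over the list alone). Those that rose most were the antiproliferative genes Btg2 (3.25 ± 0.15), Mxd1 (2.12 ± 0.13) and Gadd45a (1.57 ± 0.21), with an adjusted p of 0.0454 for the list and adjusted p = 0.259 with an estimated correlation. That list had an adjusted p of 0.052, 0.0531 and 0.0575 without mutant replicates 1, 2 and 3, 0.182 without wildtype replicate 3, and 0.059 and 0.189 without empty vector replicates 2 and 3. Its falls numbered 1 without wildtype replicates 1 or 2 or empty vector replicates 1 or 2, and 5 without wildtype replicate 3. Of 39 DNA replication genes, 5 rose, among them Ccne1 (cyclin E, 1.77 ± 0.11), and 1 fell (5 and 1 adjusted over the list alone), and the list did not pass (adjusted p 0.0806); 3 rose without wildtype replicate 1 or empty vector replicate 2 and 10 without wildtype replicate 3. The single falls in the DNA replication and mitosis lists were lost without wildtype replicates 1 or 2 or empty vector replicate 2, the former also without empty vector replicate 1 and the latter without mutant replicate 1, and both became 2 without wildtype replicate 3. Myc fell by 0.53 on the log2 scale (adjusted p 0.0105 in edgeR), a call lost without wildtype replicate 1 at an adjusted p of 0.0765, where its alternatives ran from 0.000182 to 0.0765.

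Of 27 genes of autophagy and mitochondrial clearance, 11 rose and 0 fell in edgeR (14 and 1 adjusted over the list alone), against 13 and 0 in DESeq2 and 17 members with an unadjusted p under 0.05. Without wildtype replicate 3 there was 1 fall and without empty vector replicate 3 there were 2. Atg4d (1.76 ± 0.17), Atg9a (1.37 ± 0.16) and Wipi1 (1.37 ± 0.17) led, at a camera adjusted p of 0.000554, or 0.0269 with an estimated correlation. Of 21 immediate early and stress genes, 8 rose and 7 fell (8 and 7 adjusted over the list alone), with the phosphatase Dusp1 at 3.67 ± 0.14, the stress factor Ddit3 at 2.34 ± 0.16 and Ppp1r15a at 2.23 ± 0.16. The adjusted p was 0.0175, and adjusted p = 0.167 with an estimated correlation; it was 0.0562 without empty vector replicate 1 (range 0.0056 to 0.167), and 5 rose without wildtype replicate 2 or empty vector replicate 2. Of 19 apoptosis regulators, 1 rose and 5 fell (1 and 6 adjusted over the list alone). The survival factor Bcl2l1 rose by 0.73 ± 0.12. Of 10 interferon response genes, 1 rose (Irf7, 1.21 ± 0.26) and 2 fell (1 and 2 adjusted over the list alone). Neither list passed (adjusted p 0.393 and 0.492). The falls among apoptosis regulators numbered 3 without mutant replicate 1 or wildtype replicate 2, 1 without wildtype replicate 1 or empty vector replicate 2, and 8, with 3 rises, without wildtype replicate 3; those of the interferon list numbered 1 without wildtype replicates 1 or 2 or empty vector replicate 2.

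Of 79 ribosomal protein genes, 5 rose, led by Rps14 (0.79 ± 0.21), and 0 fell in edgeR (10 and 0 in DESeq2), while 0 passed adjusted over the list alone and 25 had an unadjusted p under 0.05. The camera adjusted p of 0.000263 became an adjusted p = 0.589 with an estimated correlation. Calls in this list numbered 0 without wildtype replicate 2 (list adjusted p 0.0719, range 1.4e-08 to 0.6) or empty vector replicate 2, 3 without wildtype replicate 1, 2 without empty vector replicate 3 and 60 without wildtype replicate 3. The call of Rps14 was lost without wildtype replicate 2 or empty vector replicate 2 (alternatives 1.1e-05 to 0.084). Of 35 ribosome biogenesis genes, 5 fell, led by Ddx21 (−0.40 ± 0.11), with 0 adjusted over the list alone, 11 with an unadjusted p under 0.05 and 5 lower in DESeq2, and the list did not pass (adjusted p 0.114). The count was 0 without mutant replicate 1, wildtype replicates 1 or 2 or empty vector replicate 2, which also ended the call of Ddx21 (alternatives 0.00779 to 0.126). It was 3 without mutant replicate 2, and 8 without wildtype replicate 3 or empty vector replicate 1, where the list had an adjusted p of 0.0459 (range 0.0459 to 0.307). The 7 tested mitochondrially encoded transcripts had 0 calls in edgeR and in DESeq2, 0 adjusted over the list alone, 0 with an unadjusted p under 0.05, and a list adjusted p of 0.576. With no low-count filter, however, mt-Co1 (0.82), mt-Nd4 (0.56) and mt-Cytb (0.49) were called higher, and with 1 surrogate variable 5 of them were, and the list passed (0.0424, range 0.0424 to 0.833).

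Other fits moved the lists of the wildtype response too. With the replicate number as a block in all 9 libraries, 7 transcription factor and 3 ribosomal protein genes and 0 lymphoid markers rose. In that fit 3 ribosome biogenesis genes, 1 arrest gene and 0 genes of the heme and mitosis lists fell. With length and GC offsets, 12 DNA replication and 21 mitosis genes rose, and 11 ribosome biogenesis genes, 5 arrest genes, 2 genes each of the DNA replication, heme, membrane and autophagy lists and 1 ribosomal protein gene fell. In that fit the arrest list (0.0747, range 0.0179 to 0.259), the stress list (0.0747, range 0.0056 to 0.167) and the ribosomal protein list (0.600, range 1.4e-08 to 0.6) did not pass. With no low-count filter, 23 ribosomal protein genes and 1 ribosome biogenesis gene rose and 2 autophagy genes fell. With 1 surrogate variable, 8 DNA replication genes, 2 apoptosis regulators and 1 ribosome biogenesis gene rose, and 11 ribosome biogenesis genes, 2 DNA replication genes, 1 membrane gene and 1 autophagy gene fell. DESeq2 called 1 ribosome biogenesis gene higher. Fitted to only the 6 libraries, 3 DNA replication and 3 ribosomal protein genes and 0 lymphoid markers rose, and 3 granulocyte markers, 3 apoptosis regulators and 0 genes of the heme, mitosis and ribosome biogenesis lists fell. The fall in the heme list was also lost with RLE factors and with mutant replicates 1 and 2 summed, where 3 ribosome biogenesis genes fell. With the filter of 5 CPM in 3 libraries, 1 mast cell marker and 0 interferon genes rose.

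The mutant produced a much smaller set of changes, which included globin genes, Slc4a1 and Alas2. Slc4a1 (chromosome 11, 102348824 to 102366203) rose from 16.7 ± 2.03 to 200.4 ± 17.7 CPM (SD, n = 3), a 12-fold change. Hbb-bs rose 9.30-fold, to 713 ± 18.5 CPM, and Alas2 (chromosome X, 150547375 to 150570638) 4.03-fold, to 28.0 ± 2.94 CPM. Cpa3 fell from 31.4 ± 3.04 to 11.7 ± 1.65 CPM. Gata2 (286 ± 5.57 CPM), Kit (602 ± 43.4 CPM) and Klf1 (340 ± 23.0 CPM) were not called against the empty vector.

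In edgeR's quasi-likelihood test, 21 genes were higher and 6 lower with the mutant, and 1284 genes had an unadjusted p under 0.05. The groups did not overlap for 15% of genes, against 10% by chance if all libraries were exchangeable. The chance share is higher if mutant replicates 1 and 2 come from 1 sample, so 15% is not read as an excess. The counts depended on single libraries. Without empty vector replicate 3 there were 227 genes higher and 610 lower. Without empty vector replicates 1 or 2 there were 6 or 5 higher and 2 lower each. Without mutant replicates 1, 2 or 3 there were 10, 8 and 12 higher and 3, 2 and 2 lower, and without wildtype replicate 3 there were 11 lower. With mutant replicates 1 and 2 summed into 1 library there were 9 higher and 2 lower.

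Of the mutant's named calls, Slc4a1, Hbb-bs, Hbb-bh1, Alas2, Aqp3, Tec and Cpa3 were called under all 18 fits. Hbb-bh1, an embryonic beta-like globin, had a log2 fold change of 3.73 ± 0.33 and Aqp3, a water and glycerol channel, 1.31 ± 0.13. Tec had −1.52 ± 0.17 and Cpa3 −1.43 ± 0.16. The highest adjusted p over the alternatives was 0.0215 among these genes. Hba-a2 (2.72 ± 0.43), Hba-a1 (1.20 ± 0.17), Hbb-bt (1.49 ± 0.20), Ache (acetylcholinesterase, 1.28 ± 0.17), Slc34a3 (1.96 ± 0.27) and Bhlha15 (1.23 ± 0.20) also rose. Sgk1 (−0.85 ± 0.13), Havcr2 (−0.84 ± 0.15), Mns1 (−0.70 ± 0.12) and Ms4a2 (−3.52 ± 0.64, the beta chain of the IgE receptor, at 1.72 CPM with the empty vector) fell. Each of these 10 genes lost its call without empty vector replicate 2. So did all but Hbb-bt without empty vector replicate 1, and all but Hbb-bt and Ache without mutant replicate 2. Bhlha15, Sgk1, Havcr2, Mns1 and Ms4a2 also lost it without mutant replicates 1 or 3, and Hba-a1 without mutant replicate 1. Havcr2, Mns1 and Ms4a2 lost it without wildtype replicate 1, and Havcr2 without wildtype replicate 2. The highest adjusted p over the alternatives ran from 0.0657 for Hbb-bt to 0.276 for Havcr2.

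Of the 8 globin genes, 6 rose with the mutant (7 adjusted over the list alone), and the median log2 fold change was 2.38 with Hba-x set at its bound. That median includes Hbb-bh2, which had 0 counts with the mutant and with the empty vector, against 42 with the wildtype, so its change could not be measured. The camera adjusted p of the list was 2.4e-41, or 0.00204 with an estimated correlation. Without mutant replicate 2 or empty vector replicate 1 there were 3 calls, and without empty vector replicate 2 there were 2. Of 11 mast cell and basophil markers, 2 fell, Cpa3 and Ms4a2 (6 adjusted over the list alone), at adjusted p 1.6e-07, or 0.0267 with an estimated correlation; the count was 1 without mutant replicates 2 or 3, wildtype replicate 1 or empty vector replicates 1 or 2, and 5 without empty vector replicate 3. Of 28 genes of heme synthesis and iron handling, in edgeR only Alas2 was called (5 higher adjusted over the list alone), with Abcb10 at 0.49 ± 0.11 and Slc25a37 at 0.58 ± 0.14; the list's adjusted p was 8.2e-06 and adjusted p = 0.121 with an estimated correlation. Of 26 membrane and cytoskeleton genes, Slc4a1 rose and Mns1, a spermatogenesis-associated coiled-coil protein, fell (12 and 2 adjusted over the list alone), at adjusted p 1.3e-11 and adjusted p = 0.065 with an estimated correlation. Without empty vector replicate 3 there were 5 heme and 8 membrane genes higher, without wildtype replicate 3 there were 2 of each, and without wildtype replicate 1 there were 2 membrane genes higher.

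In the other 15 lists, edgeR called 0 members for the mutant against the empty vector, DESeq2 called 3, and 46 had an unadjusted p under 0.05. Without empty vector replicate 3, calls appeared in 11 of them. Higher and lower members then numbered 3 and 1 for erythroid transcription factors, 1 and 3 for autophagy, and 1 and 1 each for DNA replication and for immediate early and stress genes. There were 4 lower arrest genes, 3 progenitor regulators, 2 megakaryocyte markers, 1 mitosis gene and 1 apoptosis regulator, and 2 granulocyte markers and 1 ribosome biogenesis gene were higher. The 23 erythroid transcription factors had an adjusted p of 0.00618 and adjusted p = 0.317 with an estimated correlation, and 1 was higher adjusted over the list alone. The 12 megakaryocyte markers had an adjusted p of 0.00113 and adjusted p = 0.121 with an estimated correlation, and 4 were lower adjusted over the list alone, Pf4 having −0.95 ± 0.19. The remaining lists did not pass. Their adjusted p-values were 0.0584 for progenitor regulators, 0.183 for granulocyte and monocyte markers, 0.356 for DNA replication, 0.842 for mitosis, 0.17 for cell cycle arrest, 0.822 for autophagy, 0.494 for apoptosis, 0.0709 for the interferon response and 0.0536 for immediate early and stress genes. They were 0.919 for mitochondrially encoded transcripts, 0.231 for ribosomal proteins and 0.822 for ribosome biogenesis. The median and the mean differed in sign for mitosis (0.0024 and −0.02) and autophagy (0.07 and −0.03). Without empty vector replicate 1 the progenitor list (0.000523, range 0.000523 to 0.441), the stress list (0.0374, range 0.0182 to 0.33) and the ribosomal protein list (0.000523, range 0.000523 to 0.997) passed. The latter also passed without mutant replicate 3 (0.000767), and the stress list without mutant replicate 3 (0.0182), wildtype replicate 1 (0.0387) or wildtype replicate 3 (0.0383). With length and GC offsets the progenitor list passed (0.0105) and the transcription factor list did not (0.0707, range 0.000669 to 0.317). With 1 surrogate variable the mitochondrially encoded transcripts passed as higher (2.0e-05, range 2.0e-05 to 0.996). With no low-count filter, 9 membrane and 4 heme genes, 2 granulocyte, 2 stress and 1 mitosis gene were higher, and 5 mast cell, 4 progenitor, 3 megakaryocyte, 3 autophagy, 2 arrest, 1 granulocyte, 1 DNA replication and 1 stress gene lower. DESeq2 called 5 membrane, 3 heme and 1 transcription factor gene higher and 5 mast cell, 1 megakaryocyte and 1 arrest gene lower. With length and GC offsets, 2 heme and 2 membrane genes were higher, 1 progenitor, 1 megakaryocyte and 1 mast cell gene lower, and 0 membrane genes lower. With mutant replicates 1 and 2 summed, 3 globin genes were higher and 1 mast cell and 0 membrane genes lower. The replicate number as a block in all 9 libraries also left 1 mast cell and 0 membrane genes lower. There was also 1 mast cell marker lower with 1 surrogate variable or the filter of 5 CPM, and 2 membrane genes were higher with RLE factors. Adjusted over the list alone, 3 progenitor genes, 1 autophagy gene, 1 lymphoid gene, 1 granulocyte gene and 1 stress gene were lower and 2 granulocyte genes, 1 interferon gene and 1 stress gene higher.

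Of the 21 genes higher with the mutant, 13 were also higher with the wildtype, and of the 6 lower, 4 were also lower. Slc4a1, Hbb-bs, Hba-a1, Alas2, Aqp3 and Ache were among the shared rises, and Cpa3, Tec, Sgk1 and Ms4a2 were the shared falls. Independent lists of these sizes would share 2.39 and 0.713 genes. Simulated groups with no effect, sharing the same empty vector libraries, shared 0.0333 and 0 genes on average and at most 1 and 0, but such groups have almost no calls to share. With the wildtype effect kept and no effect of the mutant, 30 simulations took the 21 top genes higher and 6 lower with the mutant whether called or not. They shared 6.1 and 1.6 with the wildtype calls on average and at most 11 and 4, so the 4 shared falls do not exceed what such groups can share. The covariance of the log2 fold changes of both comparisons over genes was 0.111, against 0.0239 in the simulations, a difference of 0.0874. The simulations leave out the assumed pairing of mutant and wildtype libraries, whose like-numbered deviations add a covariance of 0.00908, leaving 0.0783. With the part of the shared empty vector libraries taken from their own deviations (0.0349) instead of the simulations, 0.0673 was left. The correlation over genes, which are not independent replicates, was 0.395 against 0.495 simulated. The shared controls were too few to split between the comparisons. The shared rises numbered 8 and 7 without mutant replicates 1 and 2, 6 and 5 without empty vector replicates 1 and 2, and 100 without empty vector replicate 3. The shared falls numbered 2 without mutant replicates 2 or 3 or empty vector replicates 1 or 2, 7 and 9 without wildtype replicates 2 and 3, and 247 without empty vector replicate 3.

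Among genes called higher with the wildtype in 2 libraries per group, the mutant's mean log2 difference from empty vector in the libraries left out was 6.73% ± 7.89 of the wildtype's (SD, 3 folds), with single values of 10.1%, 12.4% and −2.29%. For genes lower with the wildtype it was −18.8% ± 40.1, and the single values ran from −63.2% to 14.9%. The values of −2.29% and −63.2% came from replicate 3, where the wildtype's own log2 difference was small. It was 0.523 for genes higher, against 1.65 and 1.74 in the other folds, and −0.152 for genes lower, against −1.10 and −1.25. In all 3 folds the wildtype and empty vector libraries lay on opposite sides of the library trend described below. The mutant library lay on the wildtype's side each time. In replicate 3 the sides were exchanged relative to replicates 1 and 2, from which the genes of that fold were called. All 3 folds therefore carry the trend, and its part in the ratios was not separated. The filter of 5 CPM in 3 libraries gave 4.78% for genes higher and −43.0% for genes lower. A ratio of medians in place of means gave −4.29% for the genes higher.

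Measured directly against the wildtype, Hbb-bs was 23.4-fold lower with the mutant, Alas2 21.9-fold lower and Slc4a1 7.19-fold lower. Gata2 (chromosome 6, 88193891 to 88207032) was 2.78-fold and Kit (chromosome 5, 75574916 to 75656722) 2.43-fold higher with the mutant. Klf1 was lower by a log2 fold change of −0.86 ± 0.12, and Myc was higher by 0.63 ± 0.13.

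The edgeR quasi-likelihood test called 1313 genes higher and 1267 lower with the mutant than with the wildtype. The groups did not overlap for 44.2% of genes, against 10% by chance if all libraries were exchangeable. The chance share is higher if mutant replicates 1 and 2 come from 1 sample. Without mutant replicate 1 the counts were 693 and 778, without mutant replicate 2 they were 791 and 779, and without wildtype replicates 1 and 2 there were 758 and 869 higher. With mutant replicates 1 and 2 summed they were 779 and 772. With the assumed replicate pairs as a block in the 6 libraries of these groups they were 2323 and 2417. Length and GC offsets added to that fit gave 2271 and 1977.

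Among the genes lower with the mutant, Mybpc3 had 1 count with the mutant, and the wildtype exceeded it by a ratio of 2940 (counting interval 527 to 116182). Tubb1 had 2 counts, with a ratio of 927 (256 to 7664). Hba-x, Dmtn, Slc38a5 and Fam132b had log2 fold changes of −6.85 ± 0.41, −6.36 ± 0.26, −6.28 ± 0.30 and −5.16 ± 0.20. Hba-a2 (−5.31), Hbb-y (−5.08) and Hbb-bh1 (−4.96) were also lower, Hba-a2 by more than Fam132b. Among called genes with a mean of at least 5 CPM and no overlap of the groups, the genes most above the wildtype were Adgrg5, an adhesion receptor (3.72 ± 0.25), Gsn (3.15 ± 0.20), Slc34a3, a phosphate transporter (2.87 ± 0.31), Rab44 (2.43 ± 0.24), Ahnak (2.32 ± 0.28), Rrad (2.16 ± 0.22), Lcp2, Papss2, Paqr7 and Ikzf2. All these genes were called in edgeR at adjusted p-values up to 0.0038, that of Ikzf2.

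All 8 globin genes were lower with the mutant (8 adjusted over the list alone), with a median log2 fold change of −4.76 with 1 gene at its bound. Of 28 heme and iron genes, 17 were lower and 1 higher (20 and 1 adjusted over the list alone). Of 26 membrane genes, 20 were lower and 1 higher (21 and 2 adjusted over the list alone), including Rhd, an Rh blood group protein (−2.94 ± 0.14). The camera adjusted p-values were 6.7e-37, 1e-21 and 3.7e-36, and 0.00308, 0.00817 and 0.00727 with an estimated correlation. Of 23 erythroid transcription factors, 9 were lower and 3 higher (9 and 3 adjusted over the list alone), with Stat5a at 1.51 ± 0.13. The list did not pass (adjusted p 0.131), but did without wildtype replicate 2 (0.0268, range 0.0103 to 0.504). The single membrane gene higher was lost without any 1 mutant library, wildtype replicates 1 or 2, or empty vector replicate 2, and there were 2 without wildtype replicate 3. With the pairs as a block 2 membrane genes were higher; with the offsets added, 3 membrane and 2 heme genes were higher and the transcription factor list passed (0.0118).

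Of 20 progenitor regulators, 11 were higher and 1 lower (12 and 1 adjusted over the list alone), with Vim, the filament protein vimentin, at 1.62 ± 0.16. The adjusted p was 3.7e-06, and adjusted p = 0.0705 with an estimated correlation. Of 8 granulocyte and monocyte markers, 6 were higher (6 adjusted over the list alone), led by Cebpe (3.18 ± 0.38, from 0.229 to 2.19 CPM) and Tyrobp (2.55 ± 0.39), at adjusted p 0.000527, or 0.0323 with an estimated correlation; 0 were called with the filter of 5 CPM in 3 libraries. Of 12 megakaryocyte markers, 8 were higher and Tubb1 lower (8 and 1 adjusted over the list alone). The median of that list was 0.70 and its mean −0.08, and it did not pass (adjusted p 0.19); the higher members numbered 2 without mutant replicate 1 or wildtype replicate 1, 3 and 4 without mutant replicates 2 and 3, and 5 without wildtype replicate 2. Of 11 mast cell markers, 3 were higher and 2 lower (3 and 2 adjusted over the list alone), with Rab44 at 2.43 ± 0.24, Cpa3 at 1.59 ± 0.18, a median of 0.47 and a mean of −0.02; the list did not pass (adjusted p 0.131), and 1 was lower without wildtype replicate 2. With the block and offsets 5 mast cell markers were higher and 1 lower, and that list passed (0.0345, range 0.0345 to 0.548), while 1 granulocyte marker was lower. Of the 2 lymphoid markers, Gata3 was higher (1.56 ± 0.27) and Lck lower (−0.82 ± 0.24), a call lost without mutant replicates 1 or 2 or wildtype replicates 1 or 2, with adjusted p-values from 0.00203 to 0.118 over the alternatives.

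Of 39 mitosis genes, 11 were lower (14 adjusted over the list alone), with Cdc25b at −2.61 ± 0.15, at adjusted p 0.000861 and adjusted p = 0.0674 with an estimated correlation. Of 16 cell cycle arrest genes, 4 were lower and 1 higher (4 and 1 adjusted over the list alone), with Btg2 at −3.09 ± 0.15, at adjusted p 0.00486 and adjusted p = 0.16 with an estimated correlation; the higher gene was lost without mutant replicates 1 or 3, wildtype replicates 1 or 2 or empty vector replicate 2, and there were 3 without wildtype replicate 3. Of 27 autophagy genes, 11 were lower (12 lower and 2 higher adjusted over the list alone), and 0 were higher in edgeR and DESeq2 but 3 and 1 without empty vector replicates 1 and 3, with Map1lc3b, an LC3 protein of the autophagosome, at −1.07 ± 0.13; the adjusted p was 0.000756, or 0.0283 with an estimated correlation. Of 79 ribosomal protein genes, 6 were lower (0 adjusted over the list alone), with Rpl9 at −0.80 ± 0.19. Their adjusted p of 0.00174 became an adjusted p = 0.648 with an estimated correlation, 20 had an unadjusted p under 0.05 and DESeq2 called 12. The count was 2 without mutant replicates 1 or 2, 1 without mutant replicate 3 (list adjusted p 0.0693) or wildtype replicate 2 (0.24, range 1.1e-07 to 0.648), 3 without wildtype replicate 1 and 36 without wildtype replicate 3. With the pairs as a block, 44 ribosomal protein genes and 20 mitosis genes were lower, and 1 mitosis, 2 arrest and 4 autophagy genes were higher. With the offsets added, 18 ribosomal protein genes were lower and 6 higher and their list did not pass (0.350), and 2 mitosis, 4 arrest and 3 autophagy genes were higher.

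The other lists did not pass camera against the wildtype. Of 39 DNA replication genes, 6 were lower and 1 higher (5 and 0 adjusted over the list alone; list adjusted p 0.19), with Ccne1 at −1.66 ± 0.11; 2 were lower without mutant replicates 1 or 2, 3 without mutant replicate 3 or wildtype replicate 1, and 12 without wildtype replicate 3. Of 21 immediate early and stress genes, 6 were lower and 6 higher (7 and 7 adjusted over the list alone; 0.131), with Dusp1 at −3.28 ± 0.14; their median was 0.12 and their mean −0.17, and the list passed without wildtype replicate 3 (0.0458, range 0.0458 to 0.36). Of 19 apoptosis regulators, 5 were higher and 1 lower (5 and 1 adjusted over the list alone; 0.589), and of 10 interferon response genes, 5 were higher and 1 lower (5 and 1; 0.131), Bcl2l1 having −0.61 ± 0.11. In each of these lists 3 were higher without mutant replicates 1 or 3 or wildtype replicate 2 and 1 without mutant replicate 2, and without wildtype replicate 1 there were 1 and 2. The lower apoptosis genes numbered 5 without wildtype replicate 3 and 2 without empty vector replicate 3, and the lower interferon gene was lost without mutant replicates 1 or 3 or wildtype replicate 1. Of 35 ribosome biogenesis genes, 10 were higher (11 adjusted over the list alone; 0.1), with Heatr1 at 0.67 ± 0.14. That count was 2, 4 and 3 without mutant replicates 1, 2 and 3, 1 and 2 without wildtype replicates 1 and 2, and 4 without empty vector replicate 2. Of the 7 mitochondrially encoded transcripts, 0 were called in edgeR and in DESeq2 and 0 had an unadjusted p under 0.05 (list adjusted p 0.604), but with no low-count filter mt-Co1 (−0.50), mt-Nd2 (−0.58) and mt-Nd6 (−0.58) were called lower. With the pairs as a block, 17 DNA replication genes were lower and 7 higher, 6 apoptosis regulators, 3 ribosome biogenesis genes and 2 mitochondrial transcripts were lower, and the ribosome biogenesis list passed (0.049996, range 0.049996 to 0.298). With the offsets added, 14 DNA replication genes were lower and 5 higher, 5 apoptosis regulators were lower, 16 ribosome biogenesis genes were higher and 2 lower, and 5 mitochondrial transcripts were higher.

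Other fits moved the lists of this comparison as well. With the replicate number as a block in all 9 libraries, 6 megakaryocyte, 4 ribosome biogenesis and 3 interferon genes were higher. In that fit 0 membrane and 0 arrest genes were higher, and 1 mast cell marker was lower. With length and GC offsets and no block, the transcription factor list (0.0103, range 0.0103 to 0.504) and the mast cell list (0.0478, range 0.0345 to 0.548) passed and the ribosomal protein list did not (0.453, range 1.1e-07 to 0.648). In that fit 5 mast cell markers, 4 DNA replication genes, 3 membrane genes, 2 autophagy genes, 2 ribosomal protein genes and 1 mitosis gene were higher, and 10 DNA replication genes, 4 apoptosis regulators, 1 mast cell marker and 1 granulocyte marker lower. With 1 surrogate variable, 31 ribosomal protein, 19 mitosis, 15 DNA replication, 6 apoptosis and 2 ribosome biogenesis genes were lower, and 5 DNA replication, 3 membrane and 3 autophagy genes higher. With no low-count filter, 16 ribosomal protein genes and 1 ribosome biogenesis gene were lower, and 3 DNA replication, 2 membrane, 2 arrest and 2 autophagy genes higher. With mutant replicates 1 and 2 summed, 4 ribosome biogenesis, 3 megakaryocyte, 2 apoptosis and 2 interferon genes were higher, 2 DNA replication and 2 ribosomal protein genes and 0 lymphoid markers lower, and 0 membrane, DNA replication and arrest genes higher. Fitted to only the 6 libraries, 3 autophagy and 2 DNA replication genes were higher and 2 apoptosis regulators lower. There were 2 DNA replication genes higher in DESeq2 and with the filter of 5 CPM, where 1 mast cell marker and 0 interferon genes were lower, and 0 DNA replication and 6 ribosome biogenesis genes higher with RLE factors.

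**Figure D2:**
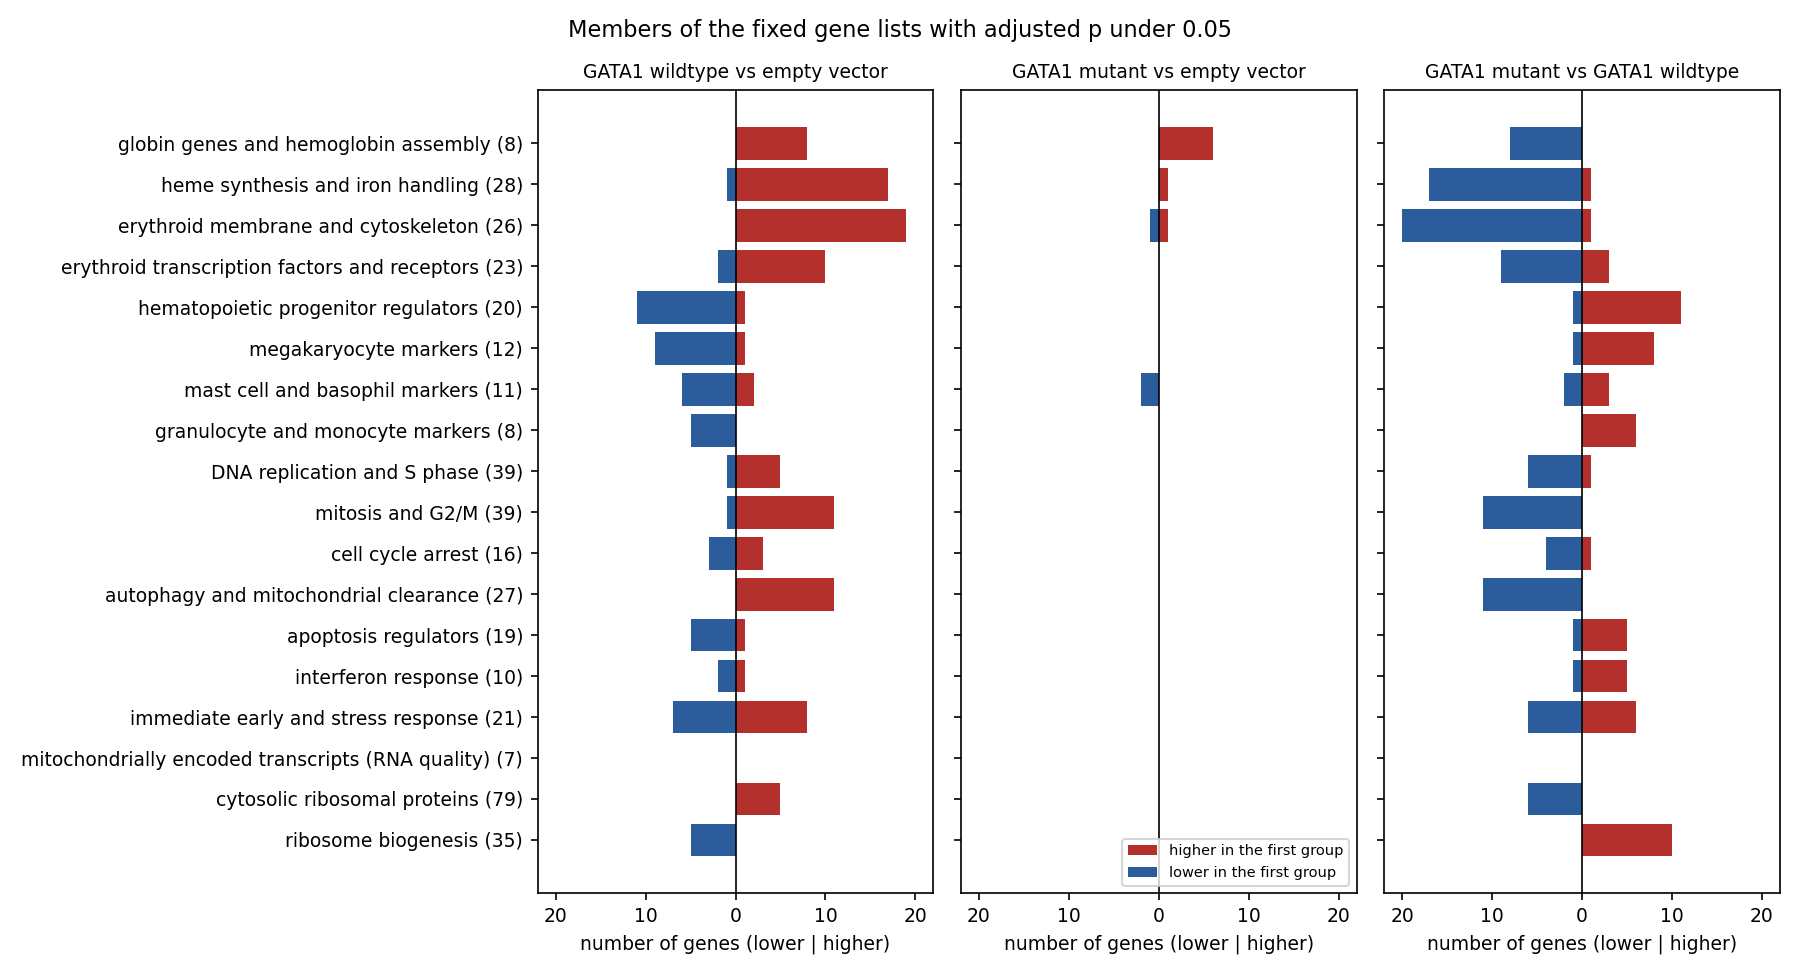
Number of members of each fixed list (tested members in parentheses) called higher (right) or lower (left) in the first group of each comparison, at an adjusted p under 0.05 in edgeR. The wildtype raised 19 of 26 membrane genes and 17 of 28 heme and iron genes, whereas the mutant raised 1 of each against the empty vector.

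The libraries also differed within groups. In a principal component analysis of log2 CPM, the first component (59.9% of the variance) parted the wildtype from the other groups, and the second (17.5%) spread the libraries within each group. The leading component of the deviations from group means took 43.9% of the variance within groups. Mutant replicate 3, wildtype replicate 3 and empty vector replicates 1 and 2 lay on one side of it and the other 5 libraries on the other. The share of mitochondrially encoded counts was 0.89%, 1.23%, 0.505% and 0.601% in those 4 libraries and between 0.313% and 0.349% in the other 5.

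**Figure D3:**
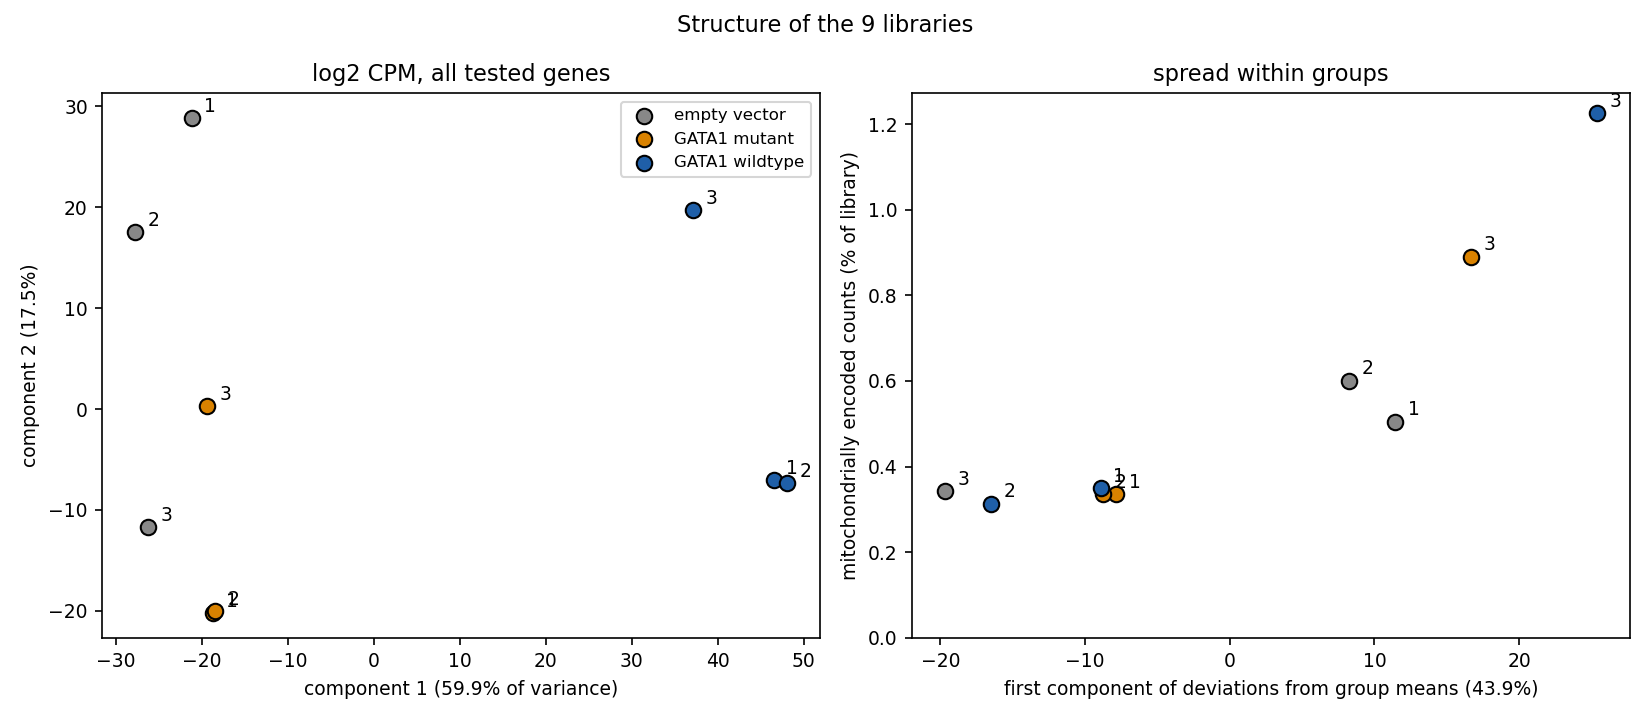
Left, the first and second principal components of log2 CPM, in arbitrary units, for the 9 libraries, coloured by group and numbered by replicate. Right, the first component of the deviations from group means (43.9% of the variance within groups) against the share of mitochondrially encoded counts, which reached 1.23% in wildtype replicate 3.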

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

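The length and GC offsets, the surrogate variable, the summed mutant replicates 1 and 2 and the block on only the 6 mutant and wildtype libraries were chosen only after the data were seen. Named genes kept their direction and side of the threshold in 3993 comparisons with an alternative, were weaker in 134 and stronger in 73, and reversed in 1. Single list tests were unchanged in 794, weaker in 32, stronger in 19 and reversed in 1; list member counts were within 1.5 times in 1812, lower in 166 and higher in 150. Counts and ratios were within range in 128, weaker in 39, stronger in 28, moved in 1 and reversed in 1.

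The wildtype comparison called 1788 genes lower with length and GC offsets. For the mutant against empty vector, genes higher and lower numbered 119 and 296 with no filter, 12 and 2 with the replicate block, 41 and 15 with length and GC offsets, 9 and 2 with replicates summed, and 58 and 37 in DESeq2; 11 were lower with 1 surrogate variable. For the mutant against wildtype, the counts were 2094 and 2047 with 1 surrogate variable, 779 and 772 with replicates summed, 2323 and 2417 with the replicate block on their 6 libraries, and 2271 and 1977 with that block and the length and GC offsets. In the last fit mt-Nd6 reversed, to a log2 fold change of 0.42 (adjusted p 0.0202, range 0.0202 to 0.734), and Spi1 was called lower (−0.27). Without the offsets the block on 6 libraries called mt-Co1 (−0.47) and mt-Nd2 (−0.38) lower. Beside these and the values in the report, the paired fits changed no other call of a named gene or list between mutant and wildtype. Shared genes higher and lower numbered 60 and 140 with no filter, 27 and 12 with length and GC offsets, 7 and 2 with replicates summed, and 35 and 30 in DESeq2; shared falls were 2 with the block and 10 with 1 surrogate variable. With an estimated correlation, 6, 2 and 5 lists passed in the wildtype, mutant and direct comparisons. The ratio of medians was −4.29% for genes higher, a reversal, and −132% for genes lower. With 1 surrogate variable the ribosomal protein list was lower with the mutant than with empty vector (p 0.00722, adjusted p 0.0162, range 0.000523 to 0.997). The cause was not tested for any of these.

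Leaving out 1 library gave 732 to 1614 genes higher and 655 to 1641 lower for the wildtype, 5 to 227 and 2 to 610 for the mutant, and 693 to 1581 and 778 to 1577 between them. Shared genes ranged from 5 to 100 higher and 2 to 247 lower, and lists past the threshold from 12 to 13, 6 to 9 and 8 to 10. Replicate numbers did not pair the empty vector libraries: their residuals correlated over genes with those of like-numbered libraries from −0.435 to −0.202 for the mutant and −0.373 to −0.222 for the wildtype, and 4 of all 9 libraries correlated best with their own number. With the replicate block in all 9 libraries, Bhlha15, Sgk1, Havcr2, Mns1, Ms4a2 and Adgrg5 were not called for the mutant against empty vector, nor Lck and Rrs1 for the wildtype. In single libraries a count of 0 allows up to the floor of 0.174 to 0.264 CPM, so expression below it could not be excluded.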

Other observations

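The tests of depth, transgene RNA, a common fraction, length and GC content and mitochondrially encoded RNA were chosen only after the results were seen.

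Adgrg5, an adhesion receptor, moved in opposite directions with the 2 forms of GATA1. It was called higher with the mutant than with the empty vector, by a log2 fold change of 1.12 ± 0.19 (SE, adjusted p 0.0359 in edgeR), and lower with the wildtype (−2.61 ± 0.27, adjusted p 1.6e-05), and it was the 1 mutant call of that kind. It was picked after its values were seen. The call with the mutant was lost in 7 of 18 alternatives, namely without any 1 mutant library, without empty vector replicates 1 or 2, with mutant replicates 1 and 2 summed, and in 1 other fit, at adjusted p-values from 0.000603 to 0.229 over all 18. That with the wildtype was kept in all, with a highest adjusted p of 0.000287.

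The mutant called 27 genes against the empty vector where the wildtype called 2323. Less depth in the mutant libraries is excluded, since the lowest mutant total was 112.866% of the highest wildtype total. Transgene RNA lowered in proportion to the response is excluded too, as the mutant mean was 79.8331% of the wildtype mean and its lowest library 65.0% of the highest wildtype library; the amount of protein was not measured and stays open. One share of cells responding as with the wildtype would give every raised gene 1 common fraction of the wildtype rise. However, 25.3521% of 71 strongly raised genes lay beyond the bounds of the best common fraction, 3.5%, against 5% allowed. The exact interval, 15.8% to 37.1%, treats genes as independent, which they are not. A single simulation gave 0%, but at another common fraction than the fitted one, with genes drawn independently and no library trend. Slc4a1 reached 12.9% ± 1.42 (SE) of its wildtype rise and Dmtn 0.838% ± 0.230, so a gene-dependent weaker activity of the mutant may be at work, as a hypothesis that these libraries cannot separate from a difference in protein amount or timing.

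Without empty vector replicate 3, 837 genes were called for the mutant against the empty vector. A trend shared by libraries of all groups is a candidate explanation: 78.5185% of 810 such genes (interval 75.5% to 81.3%) had the sign of the trend in the wildtype libraries alone, against 59.4% of the other genes. A mutant response in the direction of the wildtype response cannot be told apart: 33.9506% (interval 30.7% to 37.3%) had that sign, but the genes were picked by leaving out the same library that is subtracted in that test, so the value decides nothing. Both intervals treat genes as independent, which they are not, and the sign of the trend rests on the 3 wildtype libraries. No other biological explanation was tested.

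The library trend was taken from the leading component of the deviations from group means. Within each of the 3 groups, libraries on one side of it were compared with those on the other. These differences correlated over genes, which are not independent replicates, at 0.33, 0.43 and 0.53 between groups. The sides were chosen by that component of the same libraries, which favours positive values, so these are no separate evidence of a common trend. Transcript length and GC content accounted for 32.8507% of its variance in the wildtype libraries, so that their part and another source cannot be told apart, as the value lies between the bounds set for either. The Spearman correlation of the trend with length was −0.027 in the empty vector, 0.506 in the wildtype and 0.353 in the mutant libraries. With GC content it lay between −0.672 and −0.449. The wildtype share therefore need not hold in the other groups. Mitochondrially encoded RNA went with the trend: the lowest share among the 4 libraries at one end was 144.59% of the highest among the other 5. RNA quality or culture state may underlie both; the labels give no batch and no biological explanation was tested.

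For each comparison the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1724 genes for the wildtype against empty vector and 2849 for the mutant against wildtype, with 1 split of 10 as large in each and at most 0 genes in the others, including, for the mutant against wildtype, the 3 that part all 3 replicate pairs as the real split does. Those other splits hold both groups on both sides, so the group difference itself adds to the spread and lowers the calls. The 0 genes therefore decide little. With an unadjusted p under 0.05 in edgeR, the other splits held up to 1728 and 753 genes in these 2 comparisons, against 3076 and 4062 in the real ones. For the mutant against empty vector the real split called 28 genes and 2 of 10 splits called as many. The other, with mutant replicates 1 and 2 and empty vector replicate 3 on one side, called 1668. It parts the libraries by the sides of the library trend above. That trend was taken from these same libraries, so the count is no separate evidence of it.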
